A study of Mus musculus with 2 samples.

How the data were processed

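RNA of macrophages purified from the mouse peritoneal cavity by their surface antigen F4/80 was measured on Affymetrix MOE430A arrays. The labels give 1 array of control C3H/HeN mice and 1 array of mice infected with the bacterium Streptococcus pyogenes, so each group held 1 array. The dose, the time between infection and harvest, the number of mice behind each array and the scan dates are not given in the sources used here.

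The deposited values are intensity values on a linear scale, 1 per probe set and array, which the authors made with the Affymetrix algorithm MAS5, per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 positive signal and multiplies each array by 1 factor. Its version and settings are not given in the sources used here, and its detection calls were not used here. In the deposited values the mean over all probe sets, trimmed by 2% at each end, was 150.1 on the control array and 150.1 on the infected array, so both arrays had been brought to 1 level before deposit. A signal scaled in this way gives the share of an array's signal that a transcript takes, and a change in total RNA per cell is not visible in it.

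Both arrays held the same 22690 probe sets, of which 64 were the manufacturer's controls. Gene symbols came from the platform's annotation table. 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none in the table used, and no gene was named from a probe set with several. Of the probe sets with 1 symbol, 20364 had a gene identifier in the RefSeq gene table of the mouse assembly GRCm38.p6, and no symbol differed between the tables. The remaining 12393 genes included 4956 with several probe sets. The gene lists held 1234 symbols, and 158 of these were not tied to a single-gene probe set and are not reported here.

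The following choices were made before the data were examined. The 2% trimmed mean over the probe sets that are not controls was set equal between the arrays, which multiplied the control array by 0.999 and the infected array by 1.001. Signals below a floor were raised to it. The floor was the 40th percentile of the pooled probe sets that are not controls, a signal of 36.7. A gene was compared if it was above the floor on at least 1 array, and a gene with several probe sets was represented by the one with the highest mean log2 signal. The log2 ratio was that of infected over control. Genes at least 2-fold apart were counted as higher or lower. Where the dimmer array was at the floor, the ratio is a bound and is given as "at least". A bound under 2-fold was counted as within 2-fold, although the true ratio may be larger.

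With 1 array per group there was no test, no p-value and no replicate check. The only errors that 2 arrays allow are technical. They are the spread of the log2 ratio between the 2 brightest probe sets of a gene (the SD of their difference divided by the square root of 2) and the spread over the spiked hybridisation controls. The number of arrays limits the precision.

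46 gene lists covered 32 responses of macrophages, 13 cell types that the purified cells could include, and 1 set of genes of eye, brain, muscle and pituitary as a measure of background. For each list the median log2 ratio of the members above the floor was placed among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list was described as standing apart if its median lay outside the central 95% of the random lists and it had at least 5 such members. The percentile describes these 2 arrays and is not a p-value. The interval beside a median is the 95% order-statistic (binomial) interval over members, which covers the spread between genes only.

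The genes named were chosen by rule. They were the 15 genes with the largest increase and the 10 with the largest decrease among genes above the floor on both arrays, without those of which another probe set above the floor went the other way. To these came the 5 genes in each direction with the largest bound among those at the floor on 1 array and above 4 times the floor, a signal of 147, on the other. The 2 highest and 2 lowest members of each list, and a fixed set of cytokine, receptor and marker genes, completed the rule. Genes named outside it are said to be.

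The alternatives were values as deposited, equal medians, equal 75th percentiles, quantile normalization, removal of the intensity trend of the log2 ratio by loess, floors at the 25th and 60th percentiles, and no floor with a pseudocount of 16. Others were the median over a gene's probe sets, omission of probe sets whose identifiers end in _x_at or _s_at, thresholds of 3-fold and 4-fold, a requirement that all probe sets of a gene pass the threshold, random lists without matching, and lists without members that another list holds. One alternative, lists without members of the neutrophil list, was added after the data were seen.

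The procedure was tested on simulated data for the comparison of infected over control, with 8574 genes in the step and noise of 0.43 log2 units. Of 8376 genes without a change, 139 (1.66%) passed the 2-fold threshold. The noise was the spread between probe sets of a gene, the same for dim and bright genes. It held no variation between mice or preparations, so the share of false changes in the real arrays may be larger. Of 25 genes made higher by each factor, 12 were recovered at 2-fold, 20 at 3-fold, 25 at 4-fold and 25 at 8-fold. Of 25 made lower, 9, 16, 21 and 17 were recovered at the same factors. Of those over 4 times the floor, 6 of 14, 10 of 10, 12 of 13 and 13 of 13 were recovered. From 3-fold up the losses among genes made lower were thus mostly dimmer genes, whose drop can end at the floor. At 2-fold brighter genes were missed too, also among those made higher (7 of 11 recovered). Of brighter genes made higher, 8 of 12 were recovered at 3-fold, 11 of 11 at 4-fold and 15 of 15 at 8-fold. Of 200 random lists without a shift, 7 lay outside the central 95%, and all 10 lists shifted by 0.5 log2 units did.

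Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.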

Results

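The series asked how the transcriptome of mouse macrophages differs after infection with Streptococcus pyogenes, a Gram-positive pathogen also called group A Streptococcus. Macrophages carrying F4/80, a surface protein encoded by Adgre1, were taken from the peritoneal cavity of control and infected C3H/HeN mice, an inbred strain, and their RNA was hybridised to 1 array per group. The median signal over probe sets was 55.4 on the control array and 52.7 on the infected array, with maxima of 12574 and 14859. The floor of 36.7 was exceeded by 60.3% of probe sets on the control array and 59.7% on the infected array, and the 100 brightest probe sets took 15.1% and 16.5% of the signal. Of 12393 genes, 9049 (73.0%) were above the floor on at least 1 array and 7340 on both.

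Inflammatory transcripts set the infected array apart from the control array. Il6, Il1b, Tnfaip3, Ptgs2, Il1rn, Ccl3 and Ccl7 were each more than 80-fold higher on the infected array. The background genes of eye, brain, muscle and pituitary had 90th percentiles of 47.1 (control array) and 55.6 (infected array). Their maxima were 146 and 179. Where the dimmer signal of a gene was in that range, the size of its fold is uncertain. Cytokine and chemokine genes, targets and inhibitors of NF-kB, immediate early genes and heat shock genes had higher medians than random lists, and the metallothionein genes Mt1 and Mt2 were higher. The medians of mitosis and DNA replication genes were lower, but most ratios were within 2-fold, some of them as bounds, and the position depended on the floor. Among single genes the largest decreases were in Dusp6 (17.3-fold), Nfe2 (at least 10.99-fold), Lyl1 (9.24-fold) and Riox1 (7.98-fold). The macrophage genes Adgre1, Itgam and Lyz2 were bright on both arrays, and type I interferon-stimulated genes were not higher as a group.

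In numbers, 471 genes were at least 2-fold higher, 630 were at least 2-fold lower and 7948 lay within 2-fold, so 12.2% of the genes compared passed the threshold. In 136 of the higher and 151 of the lower genes the dimmer array was at the floor. Large differences were mostly increases. At 4-fold there were 151 higher and 31 lower genes, at 8-fold 85 and 3, at 16-fold 45 and 1, and at 64-fold 10 higher genes. At 2-fold the majority depended on the scaling: 57.2% of the genes past the threshold were lower, against 50.3% with equal medians (532 higher, 539 lower), 48.0% after quantile normalization (543 and 502), 44.3% after loess (565 and 450) and 42.3% with equal 75th percentiles (601 and 440). The median log2 ratio of all genes compared was −0.12 and moved to 0.03 with equal 75th percentiles and to −0.02 after loess, so small differences are relative to that shift.

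**Figure D1:**
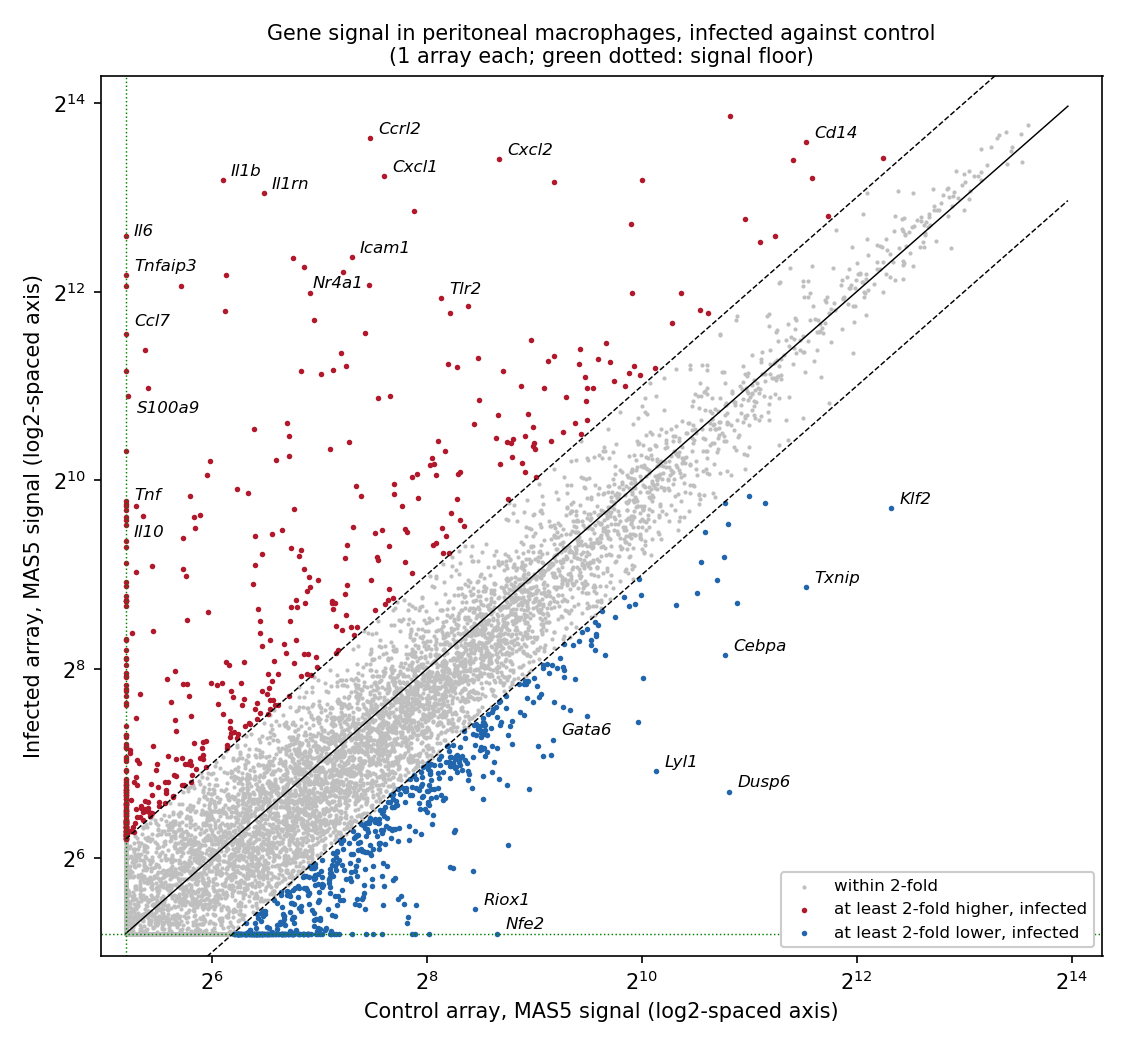
Signal of each gene above the floor on the control array (x axis) and the infected array (y axis), both on log2-spaced axes, with 1 point per gene; dashed lines mark 2-fold and green dotted lines the floor of 36.7. The 471 higher genes (red) reach farther from the diagonal than the 630 lower genes (blue), with 10 higher genes past 64-fold and 1 lower gene past 16-fold.

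The technical error was judged within the arrays, since no replicate check was possible. Over 2444 genes with several probe sets above the floor on both arrays, the log2 ratio of 1 probe set had an SD of 0.43, and the ratios of the 2 brightest probe sets correlated with Pearson's r 0.62 and Spearman's rho 0.44 across genes, which are not independent replicates. Of 118 such genes at least 2-fold higher, the second probe set was also at least 2-fold higher in 71 and went the same way in 109. Of 134 genes at least 2-fold lower, it was at least 2-fold lower in 31 and went the same way in 114. The other probe sets of Iigp1 and Ccr2, and 1 of Rsad2, went the same way as the brightest but lay within 2-fold. Those of Cxcl12 and Nusap1, and another of Rsad2, also went the same way. They gave bounds under 2-fold with 1 array at the floor, so their true ratios may be larger. For Ikbkb, Pgd and Hif1a, 1 or more probe sets, all within 2-fold, went the other way. The other probe sets of Hspa1b (1.88 and 2.29), Hdc (2.56), Ptgs2 (5.14) and Sdc4 (1.77) had smaller log2 ratios past 2-fold, and those of Clec4e (3.71) and Ptges (3.31) larger ones. The 18 spiked hybridisation controls had a mean log2 ratio of 0.12 with an SD of 0.13. The ratio of 3' to 5' signal of the control probe sets, a sign of RNA integrity, was 1.04 on the control array and 1.29 on the infected array for Actb, and 0.883 and 0.829 for Gapdh, so the ratios went opposite ways.

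Of 19 measured inflammatory cytokine genes, 12 were at least 2-fold higher and none was at least 2-fold lower. Their median log2 ratio was at least 4.41 (95% interval over members −0.06 to 6.01), above all 10000 random lists. It is a bound because the median member was at the floor on the control array. Only 9 of the 19 were above the floor on both arrays. Without members that another list holds, the median was 0.69 over 11 members (percentile 99.98). Il1b, which encodes a cytokine activated by the inflammasome, had a signal of 68.6 on the control array and 9280 on the infected array, 135-fold higher. Il1a was 64.3-fold higher (41.6 and 2674). Il6 was not above the floor in control cells and reached 6189 in infected cells, at least 168-fold higher. Tnf reached 861, at least 23.4-fold higher, and Tnfsf9, the ligand of the costimulatory receptor 4-1BB, was at least 62.4-fold higher (2294). Genes that restrain inflammation were in the same group. Il1rn, the antagonist of the interleukin 1 receptor, was 94.8-fold higher (89.4 and 8473), with log2 ratios from 3.82 to 6.57 over its 3 probe sets, and Il10 was at least 17.8-fold higher (655). The lowest members were Tnfsf13b (207 and 116) and Tgfb1 (1485 and 862), both within 2-fold. Neutrophil marker genes were higher on the same array, 9 of 16 by at least 2-fold (median log2 ratio 1.57).

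Of 17 measured chemokine genes, 7 were at least 2-fold higher, 1 was lower and 9 lay within 2-fold, and the median log2 ratio of 0.51 (−0.04 to 5.59) was at the 99.9th percentile. The higher ones included attractants of monocytes, Ccl2 (66.0-fold, 70.2 and 4638) and Ccl7 (at least 81.5-fold, 2993), and of neutrophils, Cxcl1 (49.3-fold, 195 and 9585) and Cxcl2 (26.6-fold, 408 and 10845). Ccl3 was 81.5-fold and Ccl4 48.2-fold higher. Cxcl12 was the lower one (260 and 127). Ccl5 was 61.6 in control cells, within the range of the background genes, and not above the floor in infected cells (at least 1.68-fold lower). Ccrl2, a chemoattractant receptor without known G protein signalling, was 71.1-fold higher and was among the brightest genes of the infected array (178 and 12625).

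NF-kB pathway and feedback genes had 17 of 27 members higher, none lower and a median of 1.83 (0.65 to 2.91), above all random lists. Tnfaip3, which encodes the ubiquitin-editing inhibitor A20, was at least 126-fold higher (4622 in infected cells). Nfkbiz was 33.6-fold higher (120 and 4049) and Icam1, an adhesion molecule, 33.5-fold (158 and 5280). Ikbkb (699 and 481) and Tnip2 (91.1 and 71.2) were the lowest members. Immediate early and MAPK feedback genes had 22 of 29 members higher, 2 lower and a median of 1.62 (1.16 to 3.17), also above all random lists. Nr4a1, an orphan nuclear receptor gene, was 42.3-fold higher (116 and 4901) and Egr1 24.3-fold (177 and 4306). The 2 lower members were among the strongest decreases on the arrays. Dusp6, a phosphatase of the kinase ERK, was 17.3-fold lower (1798 and 104), and Klf2, a transcription factor that restrains myeloid activation, was 6.10-fold lower (5117 and 838).

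Of 23 genes of pattern recognition receptors and adaptors, 8 were higher and none lower (median 0.21, −0.40 to 1.42; percentile 99.3), a position lost with the median over probe sets (percentile 92.4), without a floor (96.4) and without members shared with other lists (96.5). Tlr2, a receptor for bacterial lipoproteins, was 13.9-fold higher (281 and 3905) and Clec4e, the receptor Mincle, 7.01-fold (959 and 6718). Cd14 was 4.16-fold higher (2961 and 12317). Tlr4 had signals of 157 and 194, and its other probe set went the other way (log2 ratio −0.58). Myd88, the shared adaptor, was 489 and 885. Tirap was the lowest member (176 and 88.1), just within 2-fold, and its other probe set had a log2 ratio of −1.33.

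**Figure D2:**
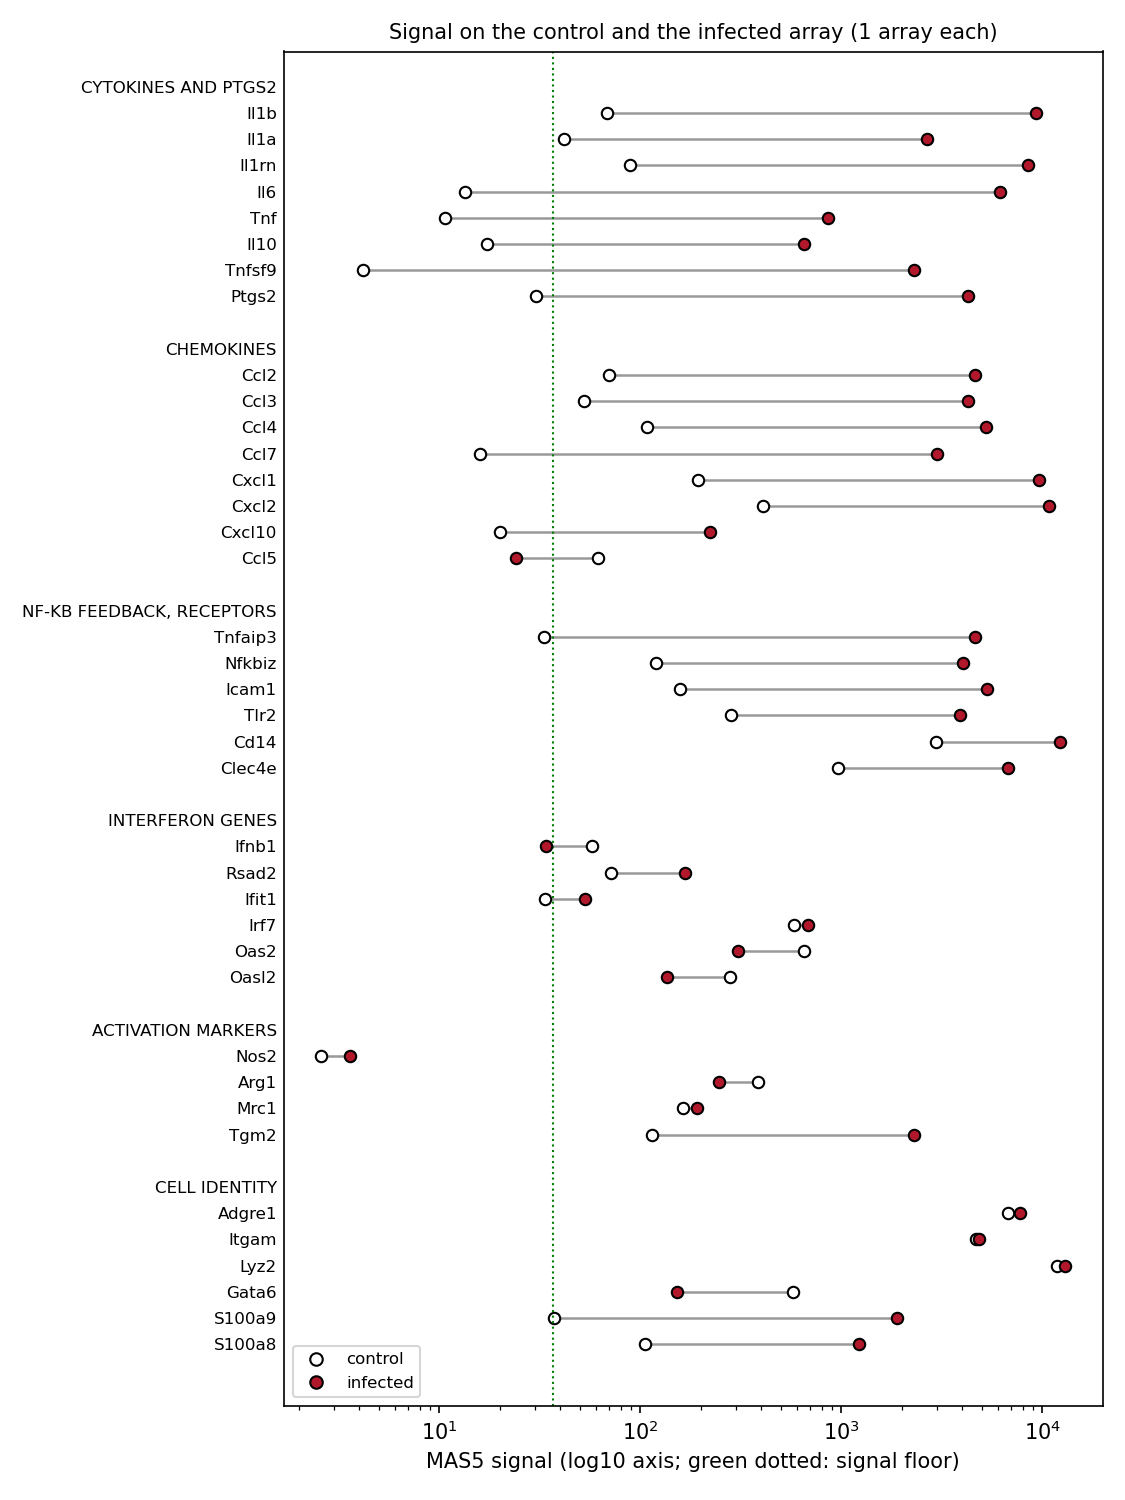
MAS5 signal (log10 axis) of named genes on the control array (open points) and the infected array (red points), 1 array each, with the floor of 36.7 as a green dotted line. Il6 runs from below the floor to 6189 and Il1b from 68.6 to 9280, whereas Nos2 stays below the floor on both arrays.

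Markers of classical (M1) activation had a median of 1.94 (−0.09 to 3.98), above all random lists, with 9 of 17 higher and 1 lower. Over the alternatives the median ranged from 0.91 to 2.10. The typical marker genes differed from each other. Nos2, the inducible nitric oxide synthase, and Il12b were not above the floor on either array (2.60 and 3.60 for Nos2, 5.69 and 34.0 for Il12b). Il6 and Il1b were the highest members, Irf5 was the lower one (510 and 240), and another probe set of Irf5 had a log2 ratio of 0.48. Socs3, a feedback inhibitor of cytokine signalling, was 15.8-fold higher (581 and 9154). Markers of alternative (M2) activation had 6 of 23 higher and none lower, with a median of 0.14 (−0.09 to 0.44; percentile 96.5) that stood apart after quantile normalization, with equal 75th percentiles and with the higher floor. Tgm2, a transglutaminase, was 20.1-fold higher (114 and 2291), and its 6 probe sets ranged from 0.03 to 5.58. Arg1 (388 and 246), Mrc1 (164 and 192) and Igf1 (357 and 206) were within 2-fold, and Chil3 was not above the floor on either array. The other probe sets of Igf1 had log2 ratios of −1.85 and 0.21.

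Interferon genes did not follow the cytokines. Of 24 measured type I interferon-stimulated genes, 1 was higher, 2 were lower and 21 lay within 2-fold, with a median of −0.35 (−0.71 to 0.04) at the 9.23rd percentile. Rsad2 was higher (71.9 and 167), Oas2 (656 and 305) and Oasl2 (280 and 136) were lower, and Ifit1 (33.8 and 53.5) and Irf7 (580 and 680) were within 2-fold. Ifnb1 was 57.7 in control cells and not above the floor in infected cells (at least 1.57-fold lower), and Ifng was not above the floor on either array. Background genes reached 146 on the control array, so that signal of Ifnb1 cannot be told from background. Interferon gamma-induced genes had 4 of 20 higher and 3 lower (median −0.22, −0.67 to 0.65; percentile 25.7). Cxcl10 was at least 6.03-fold higher (221 in infected cells) and Irf1 3.50-fold (400 and 1401). The GTPase genes Irgm2 (142 and 41.9) and Iigp1 (263 and 99.3) were lower.

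Stress response genes were higher in several groups. Heat shock and chaperone genes had 6 of 17 higher and none lower, with a median of 0.83 (0.36 to 1.21) above all random lists. Hspa1b was 7.08-fold (101 and 714) and Hspa1a 3.88-fold higher (121 and 469), while Ahsa1 (624 and 494) and Hspe1 (441 and 427) were the lowest members. Unfolded protein response genes had 2 of 25 higher and none lower (median 0.39, 0.04 to 0.75; percentile 99.97). These 2 were Atf3 (13.5-fold, 105 and 1425) and Ppp1r15a (11.04-fold, 333 and 3678), which respond to several kinds of stress, while Ddit3 (143 and 113) was within 2-fold. Oxidative stress response (NRF2 target) and metal handling genes had 8 of 23 higher and none lower (median 0.36, −0.14 to 1.40; percentile 99.9). The metallothionein genes Mt2 (31.5-fold, 235 and 7406) and Mt1 (8.22-fold, 1810 and 14874; log2 ratio 3.04, and 1.56 by its other probe set) led it. Hmox1, which encodes heme oxygenase, was 2.64-fold higher (512 and 1350), and the lowest members Pgd (1146 and 689) and Gsr (722 and 449) were within 2-fold.

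Genes of hypoxia and glycolysis had 6 of 28 higher and none lower, with a median of 0.25 (−0.08 to 0.67) at the 99.9th percentile. Hk2, a hexokinase, was 4.96-fold higher (276 and 1368), and Pfkfb3, which makes the activator of phosphofructokinase, at least 8.72-fold (320 in infected cells; log2 ratio 0.93 by its other probe set). Pfkl (1775 and 1095), Tpi1 (752 and 511), Hif1a (327 and 375) and Vegfa (51.9 and 82.9) were within 2-fold. Genes of mitochondrial metabolism lay on the other side of 0. Oxidative phosphorylation had none of 52 higher and 2 lower (median −0.18, −0.32 to −0.08; percentile 3.31), with Atp5g1 the lowest (618 and 194), and its median was −0.02 with equal 75th percentiles. It stood apart with the floor at the 25th percentile (percentile 1.76) and without _x_at and _s_at probe sets (0.19). The tricarboxylic acid cycle had none of 21 past 2-fold (median −0.37, −0.54 to 0.11; percentile 2.49), a position just outside the central range that held in 1 of 12 alternatives. Fatty acid oxidation and peroxisome genes had 1 of 25 lower and none higher (median −0.35, −0.60 to −0.08; percentile 6.82), the lower one being Cpt2 (183 and 77.9), and this list stood apart after quantile normalization and loess. Cholesterol biosynthesis genes had none of 19 past 2-fold, with a median of −0.04 that changed sign under 4 of the scalings. Among 16 cholesterol efflux and liver X receptor targets 2 were higher and none lower (median −0.18; percentile 23.3), these being Mylip (472 and 2055) and Abca1 (507 and 1321).

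Cell cycle genes had lower medians, with most ratios within 2-fold, some of them bounds. In G2/M 15 of 24 members were above the floor on both arrays, and in G1/S 17 of 22. A decrease that ended at the floor may be larger than its ratio. Of 24 genes of G2/M and mitosis, 5 were lower and 1 higher, with a median of −0.70 (−0.95 to −0.33) at the 0.01st percentile. Nusap1, which bundles spindle microtubules, was 3.43-fold lower (127 and 36.9), and Cenpa (85.01 in control cells) was at least 2.31-fold lower. The exception was Mki67, the proliferation marker Ki-67, which was 4.62-fold higher (116 and 535) by its only probe set. Genes of G1/S and DNA replication had 3 of 22 lower and none higher (median −0.48, −0.80 to −0.03; percentile 0.66), with Cdt1, a replication licensing factor, 2.5-fold lower (328 and 131). With the median over probe sets the G1/S list no longer stood apart (percentile 2.71). Most of these transcripts were dim, and with the floor at the 60th percentile neither list stood apart (percentiles 8.54 and 7.19 over 13 members each).

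Apoptosis regulators went both ways, with 5 of 24 higher and 5 lower around a median of −0.47 (−0.74 to 0.87; percentile 0.77). Gadd45b was 47.6-fold higher (42.4 and 2017; log2 ratios from 1.26 to 6.74 over 3 probe sets) and Pmaip1, the BH3-only protein Noxa, at least 22.4-fold (822 in infected cells), while Bid (170 and 49.5) and Casp2 (373 and 136) were lower. The list stood apart in 8 of 12 alternatives and lay at the 29.5th percentile with the median over probe sets.

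NADPH oxidase and antimicrobial effector genes had 5 of 21 higher and none lower (median 0.33, 0.13 to 0.81; percentile 99.9), and the calcium-binding protein gene S100a9 was 50.8-fold higher (37.4 and 1899). Its control signal was barely above the floor of 36.7, so the size of that fold is uncertain. 5 members of this list are also neutrophil markers, and without them its percentile was 97.8. Acod1, which makes itaconate, was at least 15.2-fold higher (557 in infected cells). The list no longer stood apart after loess (percentile 96.1) or without members that any other list holds (84.4, 9 members). Matrix remodelling and adhesion genes had 7 of 26 higher and none lower (median 0.47, 0.12 to 0.95; above all random lists), among them Icam1 and the proteoglycan gene Sdc4 (at least 6.62-fold, 243 in infected cells). Complement and coagulation genes had 5 of 27 higher and none lower (median 0.13; percentile 92.3). Of these, F3, the tissue factor that starts coagulation, was at least 11.6-fold higher (425 in infected cells) and Serpinb2, an inhibitor of plasminogen activators, 4.24-fold (960 and 4070). Leukotriene and prostaglandin synthesis had 3 of 16 higher and none lower (median 0.11; percentile 88.8), with Ptgs2, cyclooxygenase 2, at least 116-fold higher (4256) and Ptges, a prostaglandin E synthase, 4.49-fold (207 and 930).

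Other groups lay within the range of random lists. MHC class II presentation had none of 10 higher and 1 lower (median −0.08; percentile 33.0), the lower one being its transactivator gene Ciita (91.6 and 38.5; log2 ratio −0.11 by its other probe set). MHC class I presentation had 1 of 14 higher (median 0.04; percentile 75.4), which was H2-K1 (1494 and 3591; log2 ratios of 0.50 to 0.87 by its other 3 probe sets). Lysosome and cathepsin genes had 2 of 34 higher and 1 lower (median 0.04; percentile 74.2). Phagocytosis and Fc receptor genes had 2 of 25 lower (median −0.10; percentile 34.0), Stab1 (136 and 53.2) and Vav1 (130 and 63.0). Cytosolic ribosomal proteins had 1 of 31 higher (median 0.07; percentile 71.6), proteasome subunits none of 31 past 2-fold (median −0.25; percentile 14.8), and ribosome biogenesis and MYC targets 3 of 26 higher and 2 lower (median 0.06; percentile 95.2). The medians of both MHC lists, the lysosome, phagocytosis, ribosomal protein and prostaglandin lists changed sign under at least 1 other scaling.

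**Figure D3:**
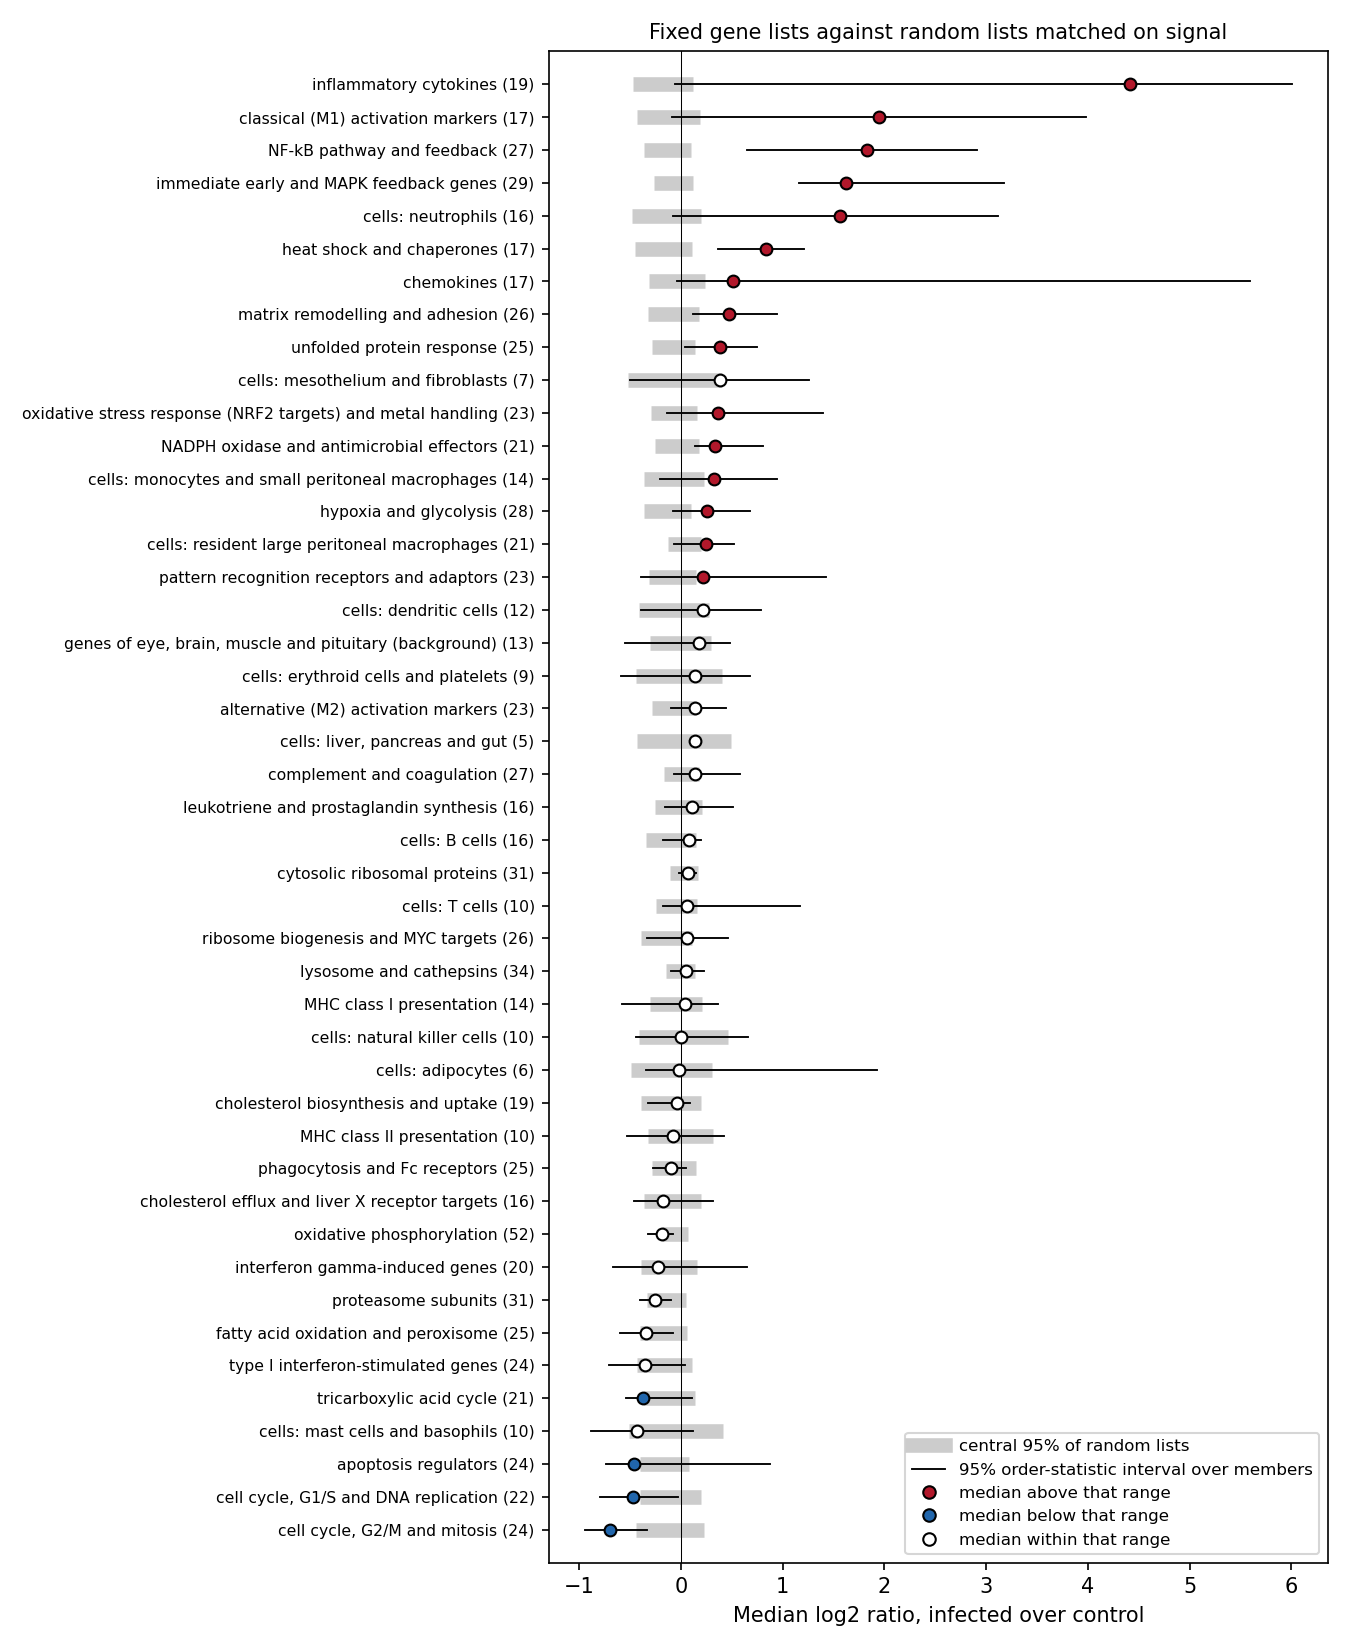
Median log2 ratio of infected over control (x axis) of each list with at least 5 measured members (number in brackets), with the 95% order-statistic interval over members as a black line (none for the 5 liver, pancreas and gut genes, too few for it) and the central 95% of 10000 random lists as a grey bar. Of 45 lists, 15 lie above their grey bar (red) and 4 below (blue).

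Of all 45 lists with enough members, 15 stood apart above and 4 below the random lists, where lists of randomly drawn genes would give 2.25. That number covers the draw of genes only, not variation between mice or arrays. 84 of the 980 genes on the lists belong to more than 1, so the lists are not independent.

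Most of the genes with the largest decreases were on none of the lists. Lyl1, a basic helix-loop-helix factor of blood cells, was 9.24-fold lower (1122 and 121), and Cebpa, a myeloid lineage factor, 6.16-fold (1749 and 284). Nfe2 (404 in control cells) was at least 10.99-fold lower, and Nr1d1, the clock repressor REV-ERB alpha, at least 6.32-fold (232). Txnip, an inhibitor of thioredoxin, was 6.32-fold lower (2958 and 468) and Sesn1, a sestrin, 5.73-fold (997 and 174). Riox1 was 7.98-fold lower, Fam43a 6.13-fold, Trim47 5.95-fold and Sertad3 5.67-fold (log2 ratio −2.50, and −0.76 by its other probe set). Tsen34 (at least 7.09-fold), Nol12 (at least 6.47-fold) and Bag5 (at least 5.22-fold) were not above the floor in infected cells. Among other large increases, Cd83, a surface marker of activated antigen-presenting cells and the highest of the dendritic cell genes, was 50.9-fold higher (69.7 and 3551) and the transcription factor gene Ets2 31.6-fold (149 and 4719).

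Markers of cell identity were compared in the same way. Adgre1 had signals of 6732 and 7710, Itgam of 4667 and 4834 and Lyz2 of 11790 and 13015, and the sign of these small differences changed with the scaling, as it did for Actb (10813 and 10493; log2 ratio 1.28 by a second, dimmer probe set). Resident large peritoneal macrophage genes had 1 of 21 higher and 1 lower (median 0.25, −0.07 to 0.52; percentile 99.015). The list did not stand apart after loess (89.2) or without members that another list holds (93.5), and after quantile normalization its median was 0.01 (98.1). The higher one was Fabp4 (184 and 699; log2 ratios from 0.44 to 1.93 over 4 probe sets). The lower one was Gata6, the transcription factor that maintains this cell type, which was 3.77-fold lower (576 and 153), with a log2 ratio of −3.26 by its other probe set. Genes of monocytes and small peritoneal macrophages had 2 of 14 higher and 1 lower (median 0.33, −0.21 to 0.95; percentile 99.3; 96.9 without _x_at and _s_at probe sets), the lower one being the chemokine receptor gene Ccr2 (174 and 67.1).

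Neutrophil genes were higher alongside the inflammatory groups. 9 of 16 measured markers were at least 2-fold higher and none lower, with a median of 1.57 (−0.07 to 3.11) above all random lists. S100a9 and S100a8 (11.7-fold, 105 and 1227) were the highest that were above the floor on both arrays, and Padi4 (2643 and 1886) and Mmp9 (197 and 157; log2 ratio 0.42 by its other probe set) were the lowest. 9 of the markers also belong to other lists, and the remaining 7 did not stand apart (median 0.16, percentile 86.1).

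Markers of other cells did not stand apart. B cell genes had none of 16 past 2-fold (median 0.08; percentile 90.6), and T cell genes had 2 of 10 higher and none lower (0.06; 82.7), which were Cd3e and Ctla4. Natural killer cell genes had 1 of 10 higher (0.00; 47.7), dendritic cell genes 2 of 12 (0.21; 94.8), erythroid and platelet genes 1 of 9 (0.14; 70.4), mesothelial and fibroblast genes 1 of 7 (0.38; 96.0), and adipocyte genes 1 of 6 (median −0.02; percentile 66.0). Mast cell and basophil genes had 1 of 10 higher and 1 lower (median −0.43; percentile 6.65). The higher one was Hdc, histidine decarboxylase, at least 11.5-fold (422 in infected cells), and the lower one the tryptase gene Tpsb2 (685 and 314). Liver, pancreas and gut genes had 1 of 5 lower (median 0.14; percentile 66.2), and only 2 eosinophil genes were measured, both within 2-fold (median 0.30). The medians of the natural killer and adipocyte lists changed sign under at least 1 other scaling. Of 41 genes of eye, brain, muscle and pituitary, 8 were above the floor on the control array (19.5%) and 9 on the infected array (22.0%), and of the 13 above it on at least 1 array none was higher and 1 lower (median 0.18; percentile 90.9).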

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

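No test was run in this part. The 2246 probe sets that are not tied to a single gene in the table used lay outside the gene comparison. Of the 1323 above the floor on at least 1 array, 76 were at least 2-fold higher on the infected array than on the control array and 66 were at least 2-fold lower. The higher ones made up 5.74% of these probe sets, against 5.21% of the genes compared, so their share was about that of the genes. The median log2 ratio of all 1323 was −0.01. Their genes were not analysed here. No outlier could be sought with 1 array per group, and no contrast was available in a second tissue, sex or time point.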

How the results depend on the processing

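The alternative without neutrophil markers was chosen after the data were seen, and the others before. No paired analysis was possible because each group held 1 array, so the groups share fewer than 2 replicate numbers, and no array could be left out. More genes passed with a lower floor, 921 higher and 1050 lower with the 25th percentile and 766 and 839 without a floor, and fewer with the 60th percentile, 306 and 336. By construction fewer passed at 3-fold, 221 and 114, and at 4-fold, 151 and 31. With every probe set of a gene required to pass, 76 higher and 34 lower genes remained of the 169 and 190 with several. With equal medians and equal 75th percentiles all 471 higher genes were kept, against 539 and 440 of the 630 lower genes. Both scalings raise the infected array relative to the control array, so their direction fixed that outcome. Quantile normalization kept 464 of the higher and 495 of the lower genes, and loess 469 and 443. The median log2 ratio rose there too, to −0.07 and −0.02.

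Of 553 list medians under the alternatives, 543 stayed within their main interval over members and none of a list that stood apart reversed. Some of these intervals are wide, so staying within them says little. The cytokine median of 0.69 (main 4.41) and the neutrophil median of 0.16 (main 1.57) counted as kept. With equal 75th percentiles the medians moved to −0.021 for oxidative phosphorylation, 0.13 for cholesterol biosynthesis, 0.063 for phagocytosis, 0.24 for ribosomal proteins and −0.091 for the proteasome. Ribosomal proteins moved to −0.16 after quantile normalization and −0.043 after loess, and the proteasome to −0.076 after loess. With the floor at the 60th percentile G2/M genes moved to −0.21 and natural killer genes to 0.73, with 13 and 1 members left. Of the 19 lists that stood apart, 10 did so in every alternative run, and 23 of the 27 others in none. Of 2053 values of 213 named genes, 1910 stayed within the spread between probe sets, 140 moved and 3 reversed. Under each scaling all 209 values compared stayed. With deposited values, equal medians and equal 75th percentiles this was fixed in advance, since 1 small factor per array moves no gene by 0.43 log2 units. Prss2 reversed to 0.15 with the median over probe sets and to 0.15 without _x_at and _s_at probe sets, and Ctse to 0.14 without them, where another probe set takes their place. Otherwise the cause was not tested.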

Other observations

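The tests on neutrophils, on scaling, on dim interferon genes and on zinc finger genes were chosen after the result was seen, and those on dim genes among the decreases, on saturation and on neighbouring genes before. The genes in the next 2 paragraphs, and Ngp, Ltf, Mmp8, Camp, Csf3r, Cd177, Clec7a, Olr1, Jdp2 and Batf further on, were named after their values were seen.

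Further members of the cytokine list were bright on the infected array alone. The colony-stimulating factor genes Csf3 (at least 34.6-fold, 1270 on the infected array) and Csf2 (at least 21.3-fold, 783) and the cytokine genes Lif (at least 24.0-fold, 880) and Il23a (at least 11.1-fold, 407) were not above the floor in control cells, nor was the growth factor gene Hbegf (at least 11.9-fold, 437). Hcar2, a receptor for ketone bodies and niacin, was 26.8-fold higher (124 and 3323), Hilpda, a lipid droplet protein gene induced by hypoxia, 16.4-fold (55.5 and 912), and the mitochondrial arginase gene Arg2 at least 17.1-fold (627), whereas Arg1 was 388 and 246. All 3 Gadd45 genes were higher, with Gadd45a 10.04-fold (53.2 and 534) and Gadd45g at least 20.1-fold (740).

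Some further bright genes were at least 4-fold lower. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was 4.55-fold lower (1888 and 415), the transcription factor gene Klf9 4.31-fold (1034 and 240). Klf10 was 5.11-fold lower (303 and 59.3). Dbp, a target of the circadian clock, had a log2 ratio of −1.22 beside the bound for Nr1d1 of −2.66, and no hour of harvest is given in the sources used here. Xist was bright on both arrays (1968 and 1858), while the Y-linked genes Eif2s3y, Kdm5d and Uty were not above the floor on either. The B cell genes Cd79a (504 and 503) and Ms4a1 (442 and 480) and the mast cell genes Cma1 (529 and 389) and Cpa3 (634 and 475) were present on both arrays. Cd3e went from 11.6 to 241, while its partner Cd3d was not above the floor (19.0 and 8.41).

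Neutrophil marker genes were higher on the infected array. The 7 markers that no other list holds did not stand apart (median 0.16, percentile 86.1). Noise of dim probe sets was not tested apart from the placing among random lists of matched signal. Neutrophils among the cells purified by F4/80, a selection that should remove them, may be the source, and of 7 measured granule protein genes 3 (Ngp, Ltf and Mmp8) were at least 2-fold higher, too few to settle it. Abundant neutrophil transcripts had mixed values, with S100a9 at 1899, Camp at 64.5, Csf3r at 805 and 765, and Cd177 at 130 and 107. Expression of these genes by the macrophages after infection was not tested and stays open.

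With the main scaling more genes were at least 2-fold lower than at least 2-fold higher. The share of lower genes among these, 57.2%, fell to 50.3% with equal medians and 48.0% after quantile normalization. After loess it was 44.3%, and with equal 75th percentiles 42.3%. The excess thus depended on how the arrays were scaled, and which scaling is right stays open. The spiked controls, which a wrong factor would lower with the genes, had a mean log2 ratio of 0.12 (hybridisation controls, SD 0.13) and 0.08 (poly-A controls, SD 0.25). Both were above the median of all genes, −0.12, by less than 2 SD, and each rests on 1 addition of controls per array. Noise of dim probe sets may also contribute. Among genes above 4 times the floor on at least 1 array the share of lower genes was 52.8% (315 higher, 353 lower). Its binomial interval of 49.0% to 56.7% includes equal numbers, but it treats genes as independent and covers no variation between arrays. Neither scaling nor noise is excluded, and a true excess of decreases after infection stays open as well.

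Type I interferon-stimulated genes were not higher while NF-kB genes were. Dim probe sets are argued against, since 85.2% of the list (23 of 27 genes on the array) were above the floor on both arrays. Saturation is argued against, since the highest control signal on the list was 1034, under the array's 99th percentile of 3872. A difference of pathway, in which the bacterium or the hour of harvest gave NF-kB targets without interferon targets, may remain as a hypothesis. The design has 1 infected array and no second time, so it was not tested.

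Among the decreases several zinc finger genes stood out, which prompted a test of all 129 measured genes with symbols starting in Zfp, Zbtb, Zkscan or Zscan. Their median of −0.25 was at the 0.76th percentile of matched random lists, with 22 at least 2-fold lower and 7 higher. Genes at least 2-fold lower and above 4 times the floor, among which the question arose, were then left out of the class and of the pool of the random lists alike, and the remaining 117 were at the 2.06th percentile. A lower level of the class passed both tests, and since these data also raised the question it stays a hypothesis. Neighbouring genes on a chromosome were taken by the order of genes in the mouse assembly GRCm38.p6. Pairs whose symbols start with the same few letters were left out, which need not remove every pair of 1 family. Clec7a with Olr1 and Jdp2 with Batf stayed in. Of 130 neighbours of genes at least 4-fold higher, 6.92% were at least 2-fold higher. This share was at the 83.0th percentile of random gene orders, whose median was 4.79%. It rests on 9 neighbours, so the test cannot decide whether neighbouring genes were higher together. Ltf is such a neighbour of Ccrl2, and its log2 ratio was 1.23.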
